A study of Mus musculus with 2 samples.

How the data were processed

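The series holds 2 single-cell libraries, wild type and Ccr2-/-, of sorted CD45+ cells from the ipsilateral hemisphere 4 days after injury. The authors deposited unfiltered matrices of UMI counts per gene and barcode, and the values are raw counts with no normalization. Reads were processed with Cell Ranger 2.0.0 on the mm10 genome, per the submitters' processing notes. Each matrix lists 27998 genes. Gene positions came from a GENCODE annotation of GRCm38, the assembly also named mm10, in which 27645 of the gene identifiers (98.7%) were found.

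Cells were called in each library as barcodes with at least the 99th percentile of UMIs among the top 3000 barcodes divided by 10, which gave minimums of 3819 and 3605 UMIs. At least 200 genes and at most 10% mitochondrial UMIs were required. Scrublet was run with an expected rate of 0.06 and marked 3 of 5407 cells, which were removed. At 0.0555% of cells the caller has not worked here, so doublets are in effect untreated, and an alternative without the 5% highest doublet scores was added. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were chosen after leaving out the interferon, MHC, dissociation, proliferation and inflammatory lists, Ccr2, Xist, mitochondrial and ribosomal genes. Both libraries were clustered together with 30 principal components, 15 neighbours and Leiden resolution 1, with no batch correction. Scanpy 1.11.5, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1 and Python 3.11.15 were used.

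Clusters were named from marker lists fixed before the data were examined. A class was open to a cluster only if 3 of its markers were found in at least 20% of the cells, and a cluster whose best scores lay within 0.15 stayed unnamed. These thresholds, and the ranking of leading genes against cells outside the class, were set after seeing the data. They leave clusters 7 and 12 unnamed, 234 wild type and 231 Ccr2-/- cells. Against all other cells, microglia-like cluster 2 (358 and 457 cells) has 2 macrophage markers and 0 microglia markers among its leading genes, and an alternative without it was added.

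Within each class with at least 50 cells in both libraries, UMIs were summed per library, expressed as CPM of the class total and compared as a log2 ratio with a prior of 0.5 counts. The interval of a ratio is the exact conditional binomial 95% interval. CPM have exact Poisson and shares exact Clopper-Pearson intervals. These cover counting error only, not variation between animals. A gene with 0 counts in 1 library was compared with a floor of 3 counts. The gene lists were fixed together with these markers, and 19 of the listed symbols, Clec7a, Mx2 and Ighm among them, are absent from the gene names used here. Members needed 20 UMIs in both libraries together, and each median was ranked among 10000 random lists matched on expression in 25 bins. The calculation was tested on simulated counts with 200 changed genes, among 9388 genes for the microglia-like class. There, 2-fold changes were recovered with a median log2 of 0.99 and 4-fold changes with 1.98, and 95.6% of intervals held the true value. The counts were Poisson draws from the pooled profile of the class. This checks the calculation and not how far the intervals hold across real cells or animals.

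The named genes were fixed by rule: among genes with at least 100 UMIs in the class and 20 CPM in a library, the 10 highest and 10 lowest ratios (5 and 5 for dendritic cell-like cells), leaving out mitochondrial, ribosomal and haemoglobin genes, Ccr2, Xist and markers of other classes. For each list, up to 4 members in the direction of its median and 1 against it could be named, and Ccr2, Ptprc and Irf7 always. Some genes that meet the rule are not reported here. The text gives a selection of the list members, chosen after their values were seen. Ccr1 outside microglia-like cells, Limd1, Sacm1l, Ppp2r3d and S100a8 fall outside the rule and were named after their values were seen. The alternatives were recomputed only for the genes named in the text, and a gene got no value where a setting left under 20 UMIs or where free RNA subtraction removed most of its UMIs, rules set after a first table was seen. To compare shares of cells with a UMI, each cell was thinned to 1000 UMIs and also to 2000 UMIs.

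Free RNA was profiled in barcodes of 1 to 50 UMIs, which hold 746296 UMIs in the wild type and 1792424 in the Ccr2-/- library. Its share in a class was first estimated as the median over markers of other classes, which gave 45.0% and 33.8% in microglia-like cells. Because many such markers are also expressed by the class, the lower quartile over markers with at least 40 free RNA UMIs was used instead, a choice made after seeing these values: 10.1% and 9.83%. The largest share that any single abundant free RNA gene allows is lower still, 6.04% and 3.85%, so the quartile removes too much for some genes. The median and the single-gene bound were added as alternatives. The most Apoe or Ccr1 that macrophage material could bring was found by linear programming over the average profiles of clusters 6, 8 and 13 and free RNA up to the bound, with 20 genes held to their upper Poisson limits in wild type microglia-like cells. Alternatives chosen before the data were examined covered cell calling at 500 and 2000 UMIs, mitochondrial limit, doublets kept, resolution, all variable genes, separate clustering, classing each cell by its own markers, scaling, cell weighting, free RNA, thinning and UMI minimums for list members.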

Results

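CD45+ leukocytes were sorted from the injured hemisphere of adult male C57BL/6 mice 4 days after a controlled cortical impact, a model of focal traumatic brain injury. Single cells were captured with the 10x Genomics 3' chemistry, which counts each RNA molecule by a unique molecular identifier (UMI). The series holds 1 wild type library and 1 library from mice that lack Ccr2, the receptor that draws inflammatory monocytes out of the bone marrow and into tissue. The libraries held 39871196 UMIs in the wild type and 32749148 in the Ccr2-/- library. After filtering, 2910 wild type cells and 2494 Ccr2-/- cells were used, with medians of 7432 and 6182.5 UMIs and of 2225 and 2023 genes per cell before the removal of 3 marked doublets. With 1 library per genotype no difference could be tested. All ranges in parentheses are 95% intervals for counting error only, exact Poisson for CPM (UMIs of a gene scaled to the UMIs of the class or library), exact binomial for shares of cells and exact conditional binomial for ratios; ranges beside list medians are taken over the members of the list. All log2 ratios are Ccr2-/- over wild type. Per the labels the wild type mice came from a vendor and the Ccr2-/- mice from a colony bred at another facility, so genotype, library and breeding site are the same split.

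Ccr2 itself was compared first. Across all cells it stood at 73.2 CPM (70.1 to 76.4) in the wild type library and 8.98 CPM (7.76 to 10.3) in the Ccr2-/- library, a log2 ratio of -3.02. In dendritic cell-like cells it stood at 387 CPM against 59.7 CPM, and in microglia-like cells at 6.88 CPM against 3.10 CPM. In monocyte/macrophage-like cells the levels lay closer, at 101 CPM (94.7 to 109) against 70.5 CPM (49.6 to 97.2). This class differs in makeup: cluster 13, led by Chil3 and Ly6c2, held 105 of 730 wild type and 21 of 55 Ccr2-/- cells. Its 2 levels therefore do not come from the same mix of cells. Ccr2 lies on chromosome 9 from 124101950 to 124113557 on the forward strand in GRCm38. The labels do not say which part of the gene the allele lacks, so 3' tags that lie outside the deleted part would still be counted, and these UMIs do not measure the protein.

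The next comparison asked which leukocytes were in the injured hemisphere with and without Ccr2. Monocyte/macrophage-like cells made up 25.1% (23.5 to 26.7) of the wild type library and 2.21% (1.67 to 2.86) of the Ccr2-/- library, 730 and 55 cells. Microglia-like cells, the resident macrophages of the brain, made up 57.4% (55.5 to 59.2) and 78.3% (76.7 to 80.0). Dendritic cell-like cells, which present antigen to T cells, made up 8.63% (7.63 to 9.70) and 6.98% (6.01 to 8.05), and 2.16% and 1.32% with each cell classed by its own markers.

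**Figure D1:**
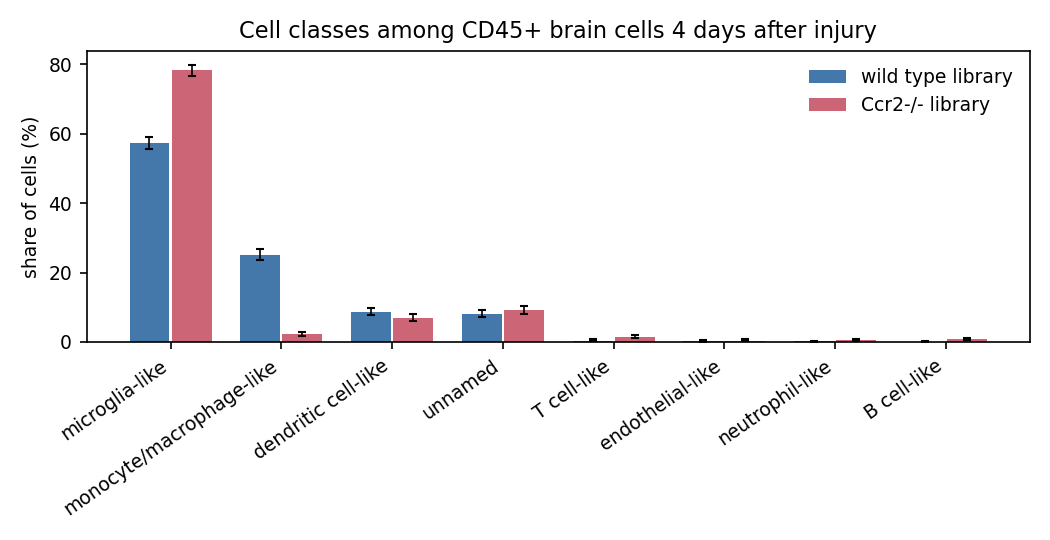
Share of cells in percent (y axis) for each cell class (x axis) in the wild type library and the Ccr2-/- library; bars are the shares and error bars exact binomial 95% intervals for counting error only. Monocyte/macrophage-like cells stand at 25.1% and 2.21%, microglia-like cells at 57.4% and 78.3%.

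Lymphocytes were few in both libraries and held a larger share in the Ccr2-/- library. T cell-like cells were 0.412% (0.213 to 0.719) of the wild type cells and 1.56% (1.11 to 2.13) of the Ccr2-/- cells, and B cell-like cells 0.0687% and 0.722%. Shares sum to 100%, so a class can stand higher because another stands lower. Among named cells outside the microglia-like and monocyte/macrophage-like classes, T cell-like cells were 12 of 277 (4.33%) and 39 of 254 (15.4%), B cell-like cells 0.722% and 7.09%, and dendritic cell-like cells 90.6% and 68.5%. Neutrophil-like cells were 4 and 13 cells and endothelial-like cells 8 and 10 cells. The endothelial-like cluster was led by Ttr, which the choroid plexus makes, then Cldn5, Itm2a and Enpp2, so it may not be endothelial alone. The T cell-like cluster was led by Nkg7, Gzma and Gzmb, with Cd3d, Cd3g and Cd3e further down. No cluster was named NK cell-like at this minimum. With a minimum of 500 UMIs an NK cell-like cluster had Gzma, Nkg7 and Gzmb among its leading genes, so the T cell-like shares may include NK cells. The B cell-like cluster was led by Jchain, Mzb1, Cd79a, Ebf1 and Vpreb3. The neutrophil-like cluster was led by S100a8, S100a9, Camp and Ngp, with Elane and Mpo further down. Whether all of these cells came from brain tissue was not tested. The UMI minimum favours large cells: with a minimum of 500 UMIs, T cell-like cells were 1.19% and 3.53%, and monocyte/macrophage-like cells 20.0% and 1.74%. Clusters 7 and 12, whose microglia and macrophage scores lay too close to name, held 8.04% of wild type and 9.26% of Ccr2-/- cells. With a stricter mitochondrial limit of 5%, 12 and 37 cells were unnamed and monocyte/macrophage-like cells made up 33.2% and 9.27%.

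The question for microglia-like cells (1669 and 1954 cells, 12352242 and 14844538 UMIs) was how the resident population differed between the libraries. Genes of the type I interferon response, which cells switch on when they sense viral or self nucleic acids, were lower in the Ccr2-/- library: 47 of 50 measured members were lower, and the list median was -0.42 (-0.47 to -0.35). Genes of the cell cycle went the other way, with all 37 measured members higher and a median of 0.43 (0.35 to 0.52). Immediate early and dissociation genes, which respond within minutes to stimulation or tissue handling, were lower for all 30 members, with a median of -0.48 (-0.65 to -0.23). This median turned to 0.28 with free RNA subtracted at the median share. By cluster it ran from -0.41 in cluster 5 to -0.10 in cluster 2, but was 0.16 in cluster 11 (21 of 28 higher). Cluster 3, with Klf2 and Egr1 among its leading genes, held 274 of 1669 wild type and 170 of 1954 Ccr2-/- cells. The homeostatic microglia list, at -0.04 (-0.11 to 0.03), and the damage-associated list, at -0.01 (-0.14 to 0.00), stood near the median of all genes, 0.03.

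Among the interferon genes, Irf7, a transcription factor that amplifies interferon production, stood at 58.1 CPM (54.0 to 62.5) in the wild type and 32.7 CPM (29.8 to 35.7) in the Ccr2-/- library, a log2 ratio of -0.83. Slfn5 was at -0.76 and Oas2, a sensor of double-stranded RNA, at -0.82. Cxcl10, a chemokine for T cells, was higher at 0.52 (0.39 to 0.64). None of the 10000 random lists matched on expression had a median as low as the interferon list. The same held for the immediate early, MHC class I and inflammatory lists, and none was as high as the cell cycle list. This rank therefore does not set the interferon list apart. Within clusters the interferon list median was -0.63 in cluster 1, -0.92 in cluster 5, -0.01 in cluster 4 and 0.02 in cluster 15, which interferon genes lead (26 of 47 higher). Irf7 had a UMI in 5.39% of wild type and 3.28% of Ccr2-/- cells thinned to 1000 UMIs, with no cell left out, and in 24.1% and 16.2% unthinned. T cell-like cells had it in 0 of 12 (at most 26.5%) and 3 of 39 thinned cells, and in 6 of 12 and 8 of 39 unthinned. Median depths were 6030 and 5691 UMIs in microglia-like cells and 6174.5 and 5039 in T cell-like cells. The shares in microglia-like cells did not stand clear of those in T cell-like cells. With 12 and 39 T cell-like cells, and a limit of 26.5% at 0 of 12, that comparison cannot decide. T cell-like cells were meant as cells that lack the gene, but 6 of 12 and 8 of 39 carried it unthinned. They may express Irf7 themselves, so they are no clean background at any number of cells. The shares are given as values and not read as shares of cells that express Irf7.

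Genes of interferon gamma and MHC class I leaned lower. The interferon gamma and guanylate-binding list was lower for 15 of 16 members, with a median of -0.19 and examples Irf1 at -0.45 and Gbp2 at -0.48. MHC class I genes, which show peptides to cytotoxic T cells, were lower for 13 of 17 members with a median of -0.17, H2-K1 among them at -0.43. H2-Q6 and H2-Q7 were at -0.90 and -0.85, but these near-identical copies share reads and are uncertain. For MHC class II genes the median was -0.08, with 8 of 12 lower, and it ran from -0.12 to 0.05 over the alternatives, so its direction is not fixed. H2-Eb1 stood at -0.75, H2-Aa at -0.58 and their chaperone Cd74 at -0.43. Free RNA carries these transcripts, and the cells it came from were not tested. With free RNA subtracted at the largest share that a single gene allows, H2-Aa stood at 0.08 and Cd74 at 0.37, while H2-Eb1 stayed lower at -0.44. The larger planned share left no usable value for any of the 3.

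For the cell cycle, Pcna, the sliding clamp of DNA replication, stood at 0.80 (0.65 to 0.95), Mcm5, part of the replicative helicase, at 0.71, Rrm2, which makes deoxynucleotides, at 0.69 (-0.15 in cells thinned to 1000 UMIs) and 2810417H13Rik at 0.72. Clusters 10 and 11, led by cell cycle genes, held 76 and 78 of 1669 wild type cells and 134 and 120 of 1954 Ccr2-/- cells. These sizes are counts from 1 library each and are not read as shares of dividing cells. With every cluster given the same weight in both libraries the list median was 0.06. Within clusters 10 and 11, found with the list left out of the genes used for clustering, the median was -0.07 (22 of 36 lower) and -0.15 (30 of 37 lower), while in the 6 other clusters it was higher: 0.33 in cluster 1, 0.47 in cluster 2, 0.54 in cluster 3, 0.08 in cluster 4, 0.37 in cluster 5 and 0.14 in cluster 15. Mki67, a marker of dividing cells, had a UMI in 3.12% (2.34 to 4.07) of wild type and 3.53% (2.76 to 4.45) of Ccr2-/- cells thinned to 1000 UMIs, and Top2a in 3.71% and 4.25%. Unthinned, Mki67 was in 9.59% and 13.7%, and Top2a in 9.11% and 14.2%. T cell-like cells had Mki67 in 0 of 12 (at most 26.5%) and 0 of 39 (at most 9.03%) thinned cells, and in 2 of 12 and 5 of 39 unthinned. In cells thinned to 2000 UMIs, Mki67 was in 4.19% (3.28 to 5.27) and 6.55% (5.49 to 7.74), and Top2a in 5.57% (4.52 to 6.78) and 6.55% (5.49 to 7.74); T cell-like cells had Mki67 in 1 of 12 and 3 of 39. At neither depth did the Mki67 shares stand clear of the upper limits in T cell-like cells. With 12 and 39 such cells these limits are too wide for the comparison to decide. T cell-like cells may also divide, and 2 of 12 and 5 of 39 carried Mki67 unthinned, so they are no clean background. The Mki67 shares are therefore not read as shares of dividing cells.

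**Figure D2:**
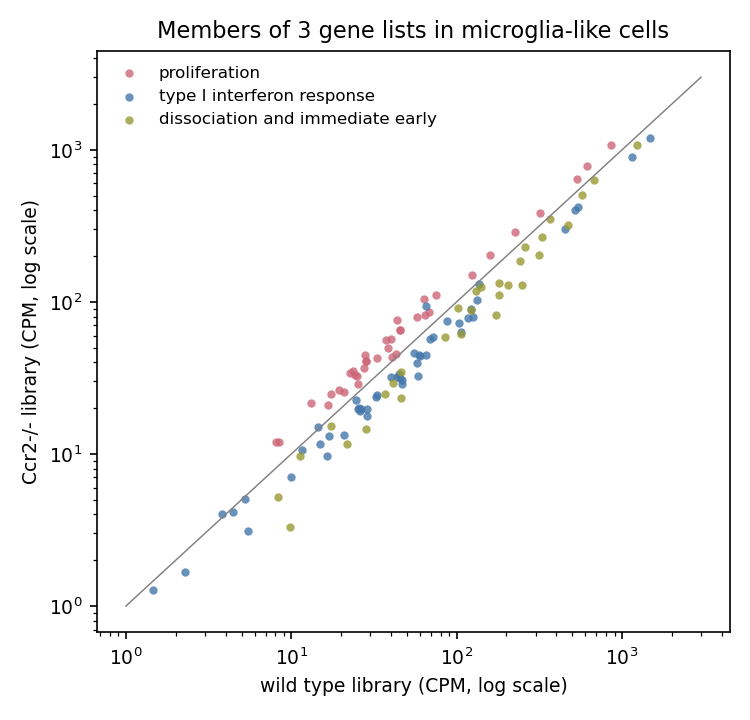
CPM in the Ccr2-/- library (y axis, log scale) against CPM in the wild type library (x axis, log scale) for members of 3 gene lists in microglia-like cells; each point is a gene and the line marks equal levels. Interferon and immediate early genes lie mostly under the line (medians -0.42 and -0.48) and cell cycle genes above it (median 0.43).

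The genes with the lowest ratios by the naming rule were Gpnmb, a glycoprotein of lipid-laden macrophages, at -2.09 (-2.29 to -1.91), then the immediate early genes Klf2 at -1.06, Egr1 at -0.98, Fosb at -0.95, Fos at -0.93 and Klf4 at -0.90. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, was at -0.89 and Ly6a at -0.86. Egr2, a further member of the immediate early list, was at -1.57. The highest were Ttr, a thyroid hormone carrier made by the choroid plexus, at 4.90, 2010315B03Rik at 1.70, Erdr1 at 1.53, the chemerin receptor Cmklr1 at 1.30 (1.05 to 1.57), the deubiquitinase Otulin at 1.09, Gm12166 at 1.07, Gng10 at 0.95, Nutf2 at 0.93, Gal3st4 at 0.93 and the metallothionein Mt2 at 0.83. Ttr stood at 53.6 CPM in wild type and 1667 CPM in Ccr2-/- barcodes of 1 to 50 UMIs, which hold free RNA. Gpnmb stood there at 576 and 73.6 CPM, against 84.4 and 19.7 CPM in the class, and its ratio was -1.08 with free RNA subtracted and -1.58 at the single-gene bound. Erdr1 has copies that reads cannot tell apart. Ptprc, which encodes CD45, was at -0.06 (-0.13 to 0.02).

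Apoe, the main lipid carrier of the brain and a damage-associated gene, stood at 17647 CPM in the wild type and 11574 CPM in the Ccr2-/- library, a log2 ratio of -0.61. Lgals3 was at -0.47 and turned to 0.20 with free RNA subtracted at the single-gene bound, and further in that direction at the larger planned share. Lilrb4a, an inhibitory receptor, was at 0.55. Markers of monocytes and macrophages were lower for 17 of 20 genes, with a median of -0.53, while 4 of 5 neutrophil markers were higher, S100a8 among them, with a median of 4.17. Of the homeostatic genes, the fractalkine receptor Cx3cr1 was at 0.10.

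The other lists in microglia-like cells had medians between -0.15 and 0.30. Inflammatory cytokines and chemokines stood at -0.13, with 20 of 28 members lower, Ccl3 at -0.48 and Ccl2 at 0.21. Alternative activation and repair stood at -0.12, with Arg1, which breaks down arginine, at -2.53, Thbs1 at -1.53, the mannose receptor Mrc1 at -1.03 and the matrix gene Fn1 at 1.12. Free RNA subtraction left no usable value for Arg1 and moved Thbs1 to 0.08, while at the single-gene bound Arg1 stood at -2.47 and Thbs1 at -0.85. Glycolysis and hypoxia stood at 0.11, with Pgk1 at 0.49. The inflammatory median turned to 0.07 with equal cluster weights, and clustering each library alone turned Pgk1, Mt2 and Lilrb4a. Complement and phagocytosis was at -0.00, oxidative stress and NADPH oxidase at 0.02, lysosome and lipid handling at -0.03 and T and NK effector genes at 0.30 over 8 members. Chemokine receptors and adhesion stood at -0.15, with Ccr1 at -4.15 (-5.09 to -3.41), 213 UMIs in the wild type and 14 in the Ccr2-/- library.

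**Figure D3:**
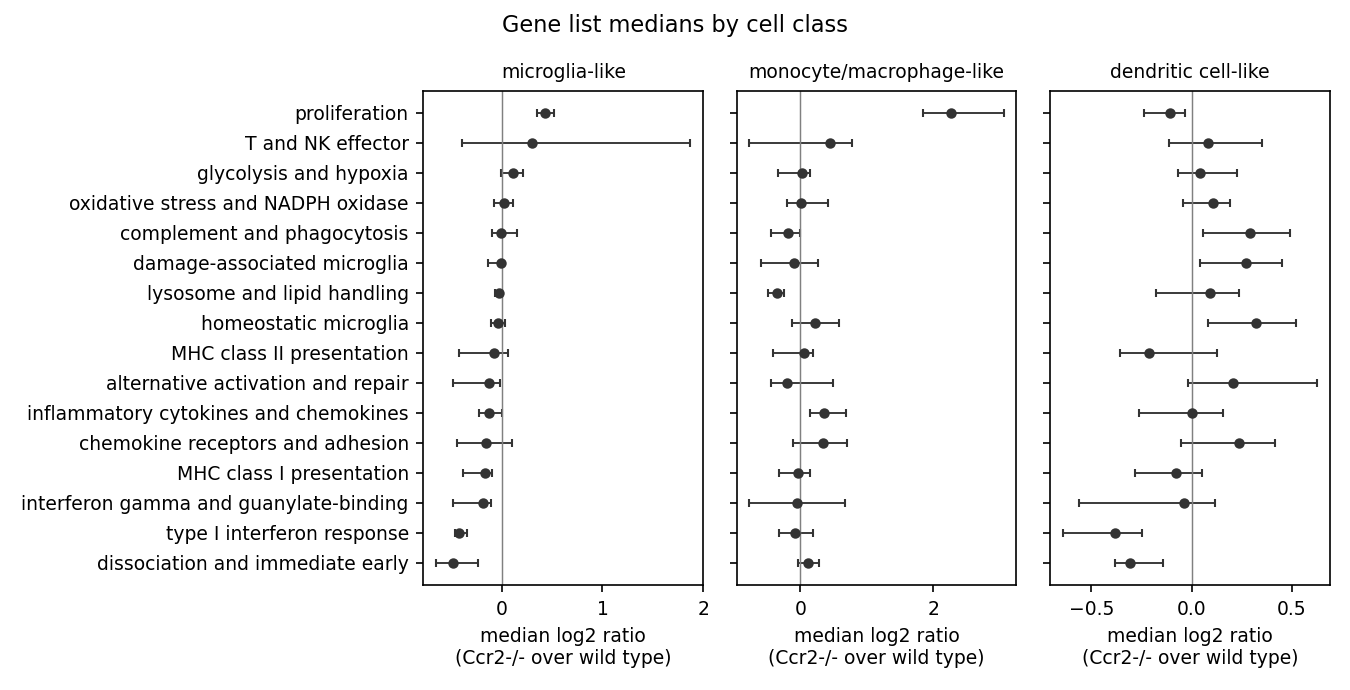
Median log2 ratio, Ccr2-/- over wild type (x axis), of each gene list (y axis) in microglia-like, monocyte/macrophage-like and dendritic cell-like cells; bars are order-statistic 95% intervals over members, not over animals. The interferon list stands at -0.42, -0.08 and -0.38.

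The 55 monocyte/macrophage-like cells left in the Ccr2-/- library were set beside the 730 of the wild type. The classes differ in makeup: cluster 13, led by Ly6c2 and Chil3, held 105 of 730 wild type and 21 of 55 Ccr2-/- cells, while clusters 6 and 8, led by Arg1, Gpnmb and Ms4a7, held 625 wild type and 34 Ccr2-/- cells. The median of all genes was 0.13, and median-of-ratios scaling shifts it by -0.10. Values in this part are therefore given relative to that median. Cell cycle genes were higher for all 37 members, with a relative median of 2.14. By cluster, uncentred, their median was 3.39 in cluster 13 (23 of 23 higher), 0.16 in cluster 6 (13 of 22) and 0.07 in cluster 8 (15 of 27). Whether the 21 Ccr2-/- cells of cluster 13 were monocytes that had entered the brain was not tested. Lysosome and lipid genes were lower for 32 of 38 members, with a relative median of -0.48.

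The highest ratios were those of Ttr at 4.30, the cell cycle genes 2810417H13Rik at 4.19, Birc5 at 3.37, Hmgb2 at 2.94, H2afx at 2.78 and Kpna2 at 2.30, the granule protease Prtn3 at 3.51, haptoglobin (Hp) at 2.34 and Ly6c2, which marks inflammatory monocytes, at 2.25. Cenpa, of the centromere, was at 2.05. Markers of other classes moved too: uncentred, the 3 dendritic cell markers were all higher with a median of 1.37, 8 of 12 microglia markers were higher with a median of 0.43, and S100a8 was at 2.14. S1pr1 had 184 UMIs in the wild type and 0 in the Ccr2-/- library, at least 3.87-fold lower against a floor of 3 counts, and Atp6v0d2 had 169 and 0, at least 3.55-fold lower. Cav2, Ttc3, Mfge8 and A930007I19Rik rested on 3 or fewer UMIs in the Ccr2-/- library, with log2 intervals before centring of -8.76 to -0.95, -5.68 to -0.76, -4.74 to -0.89 and -4.41 to -0.55. The planned free RNA subtraction left no usable value for Ttr, 2810417H13Rik, S1pr1, Atp6v0d2 and Ccl12 in this class. For S1pr1 and Atp6v0d2 this follows from their 0 UMIs in the Ccr2-/- library. Htr2b was at -2.27, Runx3 at -1.84, Pdgfa at -1.77 and Prkra at -1.77. Htr2b, Runx3 and Prkra rested on 4 UMIs each in the Ccr2-/- library and Pdgfa on 6. Runx3 turned, uncentred, to 1.11 with each cell classed by its own markers, and Prkra to 0.31 with each library clustered alone. Apoe was at -1.49, Gpnmb at -1.18, the cathepsin Ctsd at -0.98, the growth factor Igf1 at -1.08 and Apoc1 at -1.21.

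The interferon list stood at a relative median of -0.21, with 28 of 49 members lower, Irf7 at -0.99, Parp14 at -1.45 and Irf9 at 0.84. In cluster 13 alone, 40 of 43 members were lower, with an uncentred median of -1.43, while in cluster 8, with 12 Ccr2-/- cells, 35 of 45 were higher. Inflammatory cytokines stood at 0.23, with Ccl12 at 0.93, Il1a at 1.03 and the IL-1 antagonist Il1rn at -1.51. With each cell classed by its own markers the list turned to an uncentred -0.23 and Ccl12 to -0.46. Complement and phagocytosis stood at -0.32, with C1qb at -0.63. This list turned direction with all variable genes, at a mitochondrial limit of 5% and with each library clustered alone, the last to an uncentred 0.47. Mrc1 was at 1.96 and Fcrls at -0.91. Alternative activation had an uncentred median of -0.21, or 0.29 with the 2 members at 0 counts set to their bounds. Ptprc was at 0.29. Clustering each library alone turned the direction of several of these genes, Ly6c2, Mrc1, Hp, Prtn3, Ctsd, Igf1, Apoc1, C1qb and Fcrls among them, and a mitochondrial limit of 5% turned the last 5 as well.

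Dendritic cell-like cells (251 and 174 cells) shared the lower interferon genes. The list median was -0.38 (-0.64 to -0.25), with 43 of 49 members lower, and none of 10000 matched random lists was as low. The same was true of the immediate early list. Irf7 stood at 146 CPM in the wild type and 72.7 CPM in the Ccr2-/- library, with a log2 interval of -1.32 to -0.70, Ifit2 was at -1.32, Ifit3 at -1.15 and Stat2 at -1.06, while Lgals3bp was at 0.31. Immediate early genes were lower for 24 of 29 members with a median of -0.31, Klf2 at -1.10 and Egr1 at -0.98. With each cell classed by its own markers the interferon median was 0.01.

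Xcr1, a receptor of cross-presenting dendritic cells, was at -1.96 and Itgae, which the same cells carry, at -1.50. Xcr1 also lies beside Ccr2, on chromosome 9 from 123852315 to 123862029, so its value is not read as a matter of the subset alone. Cluster 14, led by Xcr1, held 85 of 251 wild type and 35 of 174 Ccr2-/- cells, and cluster 9 held 146 and 117. Irf8, which those cells need, was at -0.58, and at 0.01 with every cluster given the same weight. Ctsk, a collagen-degrading cathepsin, had 371 UMIs in the wild type and 0 in the Ccr2-/- library, at least 80.4-fold lower, and Retnla had 119 and 0, at least 25.8-fold lower. Gpnmb was at -2.16, or -1.68 with free RNA at the single-gene bound subtracted, and the fatty acid receptor Ffar4 at -1.56. The highest were Ttr at 5.52, Erdr1 at 1.89, Hivep2 at 1.84, Serpinb1a at 1.49 and Pira2 at 1.29. The planned free RNA subtraction left no usable value for Gpnmb, Ctsk, Retnla, Erdr1 and Ttr in this class. For Ctsk and Retnla this follows from their 0 UMIs in the Ccr2-/- library. In the wild type, free RNA held Ctsk at 10.7 CPM and Retnla at 0 CPM, against 150 and 48.1 CPM in the class.

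MHC class II genes in dendritic cell-like cells stood at a median of -0.21, with H2-Eb1 at -0.40 and H2-Aa at -0.36. The proliferation list stood at -0.11, with Ube2c at -1.55 and Top2a at -0.64. With each library clustered alone the list turned to 0.29 and Top2a to 0.51, and Top2a was at 0.37 with each cell classed by its own markers. The T cell subset list, with 5 members measured, stood at 0.17. The microglia lists were higher, homeostatic at 0.32 and damage-associated at 0.27, with P2ry12 at 0.60 and Spp1 at 0.73. The damage-associated median turned to -0.04 with each cell classed by its own markers, and Spp1 to -0.69 at resolution 2. The planned free RNA subtraction left no usable value for Spp1, and the single-gene bound gave 1.23. All 11 microglia markers measured in this class were higher too, with a median of 0.47. Ptprc was at -0.01.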

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

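Among the tests in this part, the subtraction of free RNA from monocytes and macrophages and the test in cells without immediate early genes were set down before their results were seen. The others were chosen after values they bear on had been seen: free RNA and equal cluster weights for the interferon genes, free RNA at the single-gene bound for Apoe and the macrophage markers, the share of macrophage RNA, the macrophage clusters and their mixes for Apoe and Ccr1, and the genes around Ccr2.

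Barcodes of 1 to 50 UMIs, which no comparison of cells uses, held Ttr at 1667 CPM in the Ccr2-/- library and 53.6 CPM in the wild type. The same barcodes held the neutrophil gene S100a8 at 387 CPM and 65.7 CPM. Clustering anew with a minimum of 500 UMIs gave 158 more T cell-like barcodes in the Ccr2-/- library and 53 more in the wild type. It also gave 68 and 19 more B cell-like barcodes, and 30 and 20 NK cell-like barcodes. No cluster was named NK cell-like at the main minimum, so the T and NK counts can include cells that changed name. These values drew attention as signals largely outside the cells that were compared, and all lie above the 3 counts that a count of 0 allows.

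Type I interferon genes were lower in the microglia-like cells of the Ccr2-/- library, with a median of -0.42. Free RNA from other cells as the whole cause is argued against by the median after its subtraction, -0.40 (-0.48 to -0.37), and by -0.41 with the single-gene bound of 6.04% taken from the wild type alone, although the largest free RNA estimate turned Irf7 itself to 0.97. In cells with no UMI of 6 immediate early genes (676 and 1018 cells) the median was -0.59 (-0.67 to -0.42). By the bound set beforehand this argues against handling as far as cells with these transcripts carry it. Cells can lack such UMIs through low depth, so it cannot exclude handling that shifted a whole library. With equal cluster weights the median was -0.38 (-0.42 to -0.32), which argues against another mix of the microglia-like clusters as the whole cause. The clustering left out the interferon list, so this cannot exclude another number of interferon-responding cells within clusters. Cluster 15, led by interferon genes, held 44 of 1669 wild type and 31 of 1954 Ccr2-/- cells. With a minimum of 500 UMIs, a microglia-like cluster led by such genes held 245 of 3851 and 105 of 4784 cells. A different number of such cells stays open. The genotype stays open as a hypothesis, and so do the breeding site, the animals and the library with its handling, which the design cannot separate from it.

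Macrophage transcripts and Apoe were lower in the same cells, for which free RNA or macrophage cells in the wild type class could account. The first free RNA test is void, because it put the wild type share at 59.9%, above the single-gene bound of 6.04%, and left 5 of 20 markers, with a median of -0.31 (-1.88 to 1.09). With the bound taken from the wild type alone Apoe stayed at -0.50 (-0.51 to -0.49), which argues against free RNA as its whole cause, while the markers stood at -0.22 (-0.59 to 0.31), which leaves free RNA open for them. For macrophage RNA of any kind, Apoe needs a share of 9.25%, which is 3.90, 1.82 and 0.10 times the smallest, median and largest share that a marker allows; the bound was worded so that each of these could be meant, a first reading by the median had excluded the explanation, and with the readings apart it decides nothing. By cluster, the lowest percent of markers under the level that Apoe needs was 11.8%, in cluster 8 (2 of 17 markers), and with every marker within its upper limit a mix of clusters 6, 8 and 13 and free RNA could bring at most 77.0% of the Apoe difference, short of all but not far below, so such cells stay open beside a lower level in microglia themselves.

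Ccr1, which lies beside Ccr2 on chromosome 9, was at -4.15 in microglia-like cells, -0.39 in monocyte/macrophage-like cells and 0.24 in dendritic cell-like cells, where Xcr1, beside Ccr2 as well, was at -1.96. The share of macrophage RNA it needs, 14.7%, was 6.19, 2.89 and 0.159 times the smallest, median and largest share that a marker allows, which alone decides nothing for the same reason, and by cluster the needed shares were 18.1% in cluster 6, 19.9% in cluster 8 and 3.93% in cluster 13, with 9 of 17, 6 of 16 (37.5%) and 7 of 15 markers under the level they would bring. In clusters 8 and 13 most markers reached that level, which by the rule of that test goes with macrophage cells as a cause. The mix is stricter, since it holds every marker and Apoe within their upper limits. A mix of these clusters and free RNA brings at most 34.5% of the Ccr1 difference. This argues against macrophage cells and RNA as its whole cause, as far as the cluster averages describe such cells. For a change carried beside the targeted gene, the 11 genes within 1 Mb had a median absolute log2 ratio of 0.19 against 0.13 in random sets, at percentile 86.7, below the 90 set for arguing against this explanation, but it is read as undecided, a reading chosen after the value was seen, since a carried change could touch few genes and 4 of the 11 were beyond 0.5. The genotype and a carried change stay open for Ccr1, and they were not tested apart for Xcr1, which stood at -1.03 with equal cluster weights.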

How the results depend on the processing

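No paired analysis was possible because each genotype has 1 library and no result comes from a test. Ccr2, the shares of microglia-like and monocyte/macrophage-like cells and 5 list medians make up 11 results. They stayed within their intervals under 130 alternatives and moved beyond them under 47. A turn could be called only for the interferon and proliferation medians in microglia-like cells, and neither turned. The rest of the 11 are levels and shares, which cannot turn, or medians whose intervals hold 0. For the other results, 2516 values stayed within their intervals (2424 in the same direction), 665 moved (625 in the same direction) and 52, of 35 results, turned direction. The interferon median in microglia-like cells kept its sign under all 22 alternatives, between -0.56 and -0.31, and the proliferation median did so between 0.06 and 0.55. The interferon median in monocyte/macrophage-like cells ran from -0.37 to 0.07, so its direction is not fixed. The damage-associated median ranged from -0.30 to 0.02 and the homeostatic median from -0.30 to 0.23, so neither direction is fixed. Monocyte/macrophage-like cells ranged from 18.8% to 33.2% in the wild type and from 1.74% to 9.27% in the Ccr2-/- library. Dendritic cell-like cells ranged from 2.16% to 8.85% and from 1.32% to 7.10%, lowest with each cell classed by its own markers. T cell-like cells ranged from 0% to 1.19% and from 0% to 3.53%, at 0% where no cluster was named as T cells, and B cell-like cells from 0% to 0.385% and from 0.241% to 1.54%. The 55 Ccr2-/- cells of that class limit every value within it. Free RNA at the median share or at the single-gene bound, equal cluster weights, the removal of high doublet scores, the naming of close clusters and the removal of a cluster led by other markers were chosen after seeing the data. For some genes free RNA subtraction left no value.

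For these 11 results the values that moved, and for all others the values that turned direction, were as follows, and the cause was not tested; the 665 other values that moved are only counted above. Values for monocyte/macrophage-like cells here are uncentred, and those of Runx3 at 0.075, Prkra at 0.0019 and 0.11 and the complement list at 0.025 lie below the main median of all genes in that class, 0.13, so relative to it they did not turn. With all barcodes, Ccr2 in the wild type was at 68.0 CPM. With all variable genes, microglia-like cells were 76.0% of Ccr2-/- cells and monocyte/macrophage-like cells were 28.3% of wild type and 3.69% of Ccr2-/- cells. In monocyte/macrophage-like cells C1qb turned to 0.22, Fcrls to 0.55 and the complement and phagocytosis list to 0.24. With barcodes of at least 2000 UMIs, microglia-like cells were 64.7% of wild type and 83.7% of Ccr2-/- cells, monocyte/macrophage-like cells were 22.1% of wild type cells and the type I interferon response list in microglia-like cells moved to -0.56. With barcodes of at least 500 UMIs, microglia-like cells were 70.6% of wild type and 85.8% of Ccr2-/- cells, monocyte/macrophage-like cells were 20.0% of wild type cells and the type I interferon response list in microglia-like cells moved to -0.53. In cells thinned to 1000 UMIs, the proliferation list in microglia-like cells moved to 0.30 and the type I interferon response list in microglia-like cells moved to -0.48. In microglia-like cells Ccl2 turned to -0.037 and Rrm2 to -0.15. Among monocyte/macrophage-like cells Runx3 turned to 0.075. Among dendritic cell-like cells the proliferation list turned to 0.077. With the unnamed clusters given their closest class, microglia-like cells were 65.4% of wild type and 87.6% of Ccr2-/- cells. With each cell classed by its own markers, microglia-like cells were 78.2% of wild type and 92.5% of Ccr2-/- cells, monocyte/macrophage-like cells were 18.8% of wild type and 4.49% of Ccr2-/- cells, the homeostatic microglia list in microglia-like cells moved to 0.23, the proliferation list in microglia-like cells moved to 0.55 and the type I interferon response list in microglia-like cells moved to -0.31. In monocyte/macrophage-like cells Ccl12 turned to -0.46, Prkra to 0.11, Runx3 to 1.11 and the inflammatory cytokines and chemokines list to -0.23. Among dendritic cell-like cells Top2a turned to 0.37, the complement and phagocytosis list to -0.15, the damage-associated microglia list to -0.036 and the type I interferon response list to 0.0088. In microglia-like cells the inflammatory cytokines and chemokines list turned to 0.014. With each library clustered alone, microglia-like cells were 62.6% of wild type and 71.6% of Ccr2-/- cells, monocyte/macrophage-like cells were 19.7% of wild type and 7.46% of Ccr2-/- cells, the damage-associated microglia list in microglia-like cells moved to -0.30, the homeostatic microglia list in microglia-like cells moved to 0.16, the type I interferon response list in microglia-like cells moved to -0.33 and the type I interferon response list in monocyte/macrophage-like cells moved to -0.35. Among monocyte/macrophage-like cells Apoc1 turned to 0.71, C1qb to 0.70, Ctsd to 0.54, Fcrls to 1.97, Hp to -0.50, Igf1 to 1.13, Ly6c2 to -0.62, Mrc1 to -0.55, Prkra to 0.31, Prtn3 to -0.65 and the complement and phagocytosis list to 0.47. In microglia-like cells Lilrb4a turned to -0.41, Mt2 to -0.18 and Pgk1 to -0.025. Among dendritic cell-like cells Top2a turned to 0.51 and the proliferation list to 0.29. With equal cluster weights, the damage-associated microglia list in microglia-like cells moved to 0.0037 and the proliferation list in microglia-like cells moved to 0.055. In dendritic cell-like cells Irf8 turned to 0.0071. In monocyte/macrophage-like cells the complement and phagocytosis list turned to 0.025. In microglia-like cells the inflammatory cytokines and chemokines list turned to 0.070. With free RNA subtracted, the damage-associated microglia list in microglia-like cells moved to 0.0021. In microglia-like cells Lgals3 turned to 1.11 and Thbs1 to 0.083. With free RNA subtracted at the median share, the damage-associated microglia list in microglia-like cells moved to 0.024, the homeostatic microglia list in microglia-like cells moved to -0.30 and the proliferation list in microglia-like cells moved to 0.32. In microglia-like cells Cx3cr1 turned to -0.17, Irf7 to 0.97, the alternative activation and repair list to 0.063 and the dissociation and immediate early list to 0.28. With free RNA at the single-gene bound, in microglia-like cells Cd74 turned to 0.37, H2-Aa to 0.079 and Lgals3 to 0.20. With the mean of each cell's CPM, the damage-associated microglia list in microglia-like cells moved to 0.0075 and the proliferation list in microglia-like cells moved to 0.29. With mitochondrial UMIs at most 5%, microglia-like cells were 80.5% of Ccr2-/- cells, monocyte/macrophage-like cells were 33.2% of wild type and 9.27% of Ccr2-/- cells and the type I interferon response list in monocyte/macrophage-like cells moved to -0.37. Among monocyte/macrophage-like cells Apoc1 turned to 0.77, C1qb to 0.34, Ctsd to 0.33, Fcrls to 0.86, Igf1 to 0.56, Prkra to 0.0019 and the complement and phagocytosis list to 0.32. At resolution 0.5, microglia-like cells were 65.0% of wild type and 87.5% of Ccr2-/- cells. At resolution 2, microglia-like cells were 80.1% of Ccr2-/- cells. In dendritic cell-like cells Spp1 turned to -0.69. Without the top 5% of doublet scores, microglia-like cells were 61.8% of wild type cells.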

Other observations

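The comparison of genes around Ccr2 was chosen after its values had been seen.

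Around Ccr2 in microglia-like cells, 2010315B03Rik was at 1.70, Limd1 at 0.67, Sacm1l at 0.26, Ppp2r3d at -0.19 and Ccr1 at -4.15. The median absolute log2 ratio of the 37 genes within 5 Mb was 0.12, against 0.13 in random sets. In dendritic cell-like cells the median of the 7 genes within 1 Mb was 0.22, against 0.19.

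Among markers of other cell types in microglia-like cells, the 4 oligodendrocyte genes measured were lower in the Ccr2-/- library, with a median of -0.46, and the 4 erythroid genes were higher, with a median of 0.29. The 3 plasmacytoid dendritic cell genes were lower, with a median of -0.22. Within the microglia-like clusters led by cell cycle genes, the interferon median was -0.63 in cluster 10 and -0.49 in cluster 11.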
